A study of Homo sapiens with 13 samples.

How the data were processed

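MCF10A cells, a non-tumorigenic human mammary epithelial line, were transduced with libraries of guide RNAs against tumour suppressor genes and profiled as single cells 24 h after mock treatment or doxorubicin, a topoisomerase poison that breaks DNA. The series holds 13 samples. There were 5 single-cell RNA libraries and 8 sorted cell populations whose integrated barcodes were read as amplicons. In 3 single-cell libraries the guide was identified by a linked barcode on a separate transcript (barcoded vector), and in the other 2 the guide itself was carried on a polyadenylated transcript (CROP-seq vector). Each of the 13 groups named by the labels had 1 sample, and treatment, dose, vector and virus production were taken from the sample titles and protocol labels. The dose was 500 nM in the barcoded-vector libraries and 100 nM in the CROP-seq library.

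Per the submitters' processing notes, single-cell reads were processed with Cell Ranger against hg19; its version and the gene annotation release are not given in the sources used here. The deposited matrices hold UMI counts per gene and cell barcode for 32738 genes as the authors called them. They were whole numbers, and their sums per cell equalled the totals in the deposited cell metadata. The 3 barcoded-vector libraries share 1 aggregated matrix, and whether their reads were thinned to a common depth is not given in the sources used here. The cell metadata made by the authors list the guides or barcodes assigned to each cell, their UMI counts and, as a fraction, their share of the guide reads of the cell; the thresholds for assignment are not given in the sources used here. For the sorted populations the deposited table holds counts of reads with the BFP-linked and GFP-linked barcode, and each of these as a fraction of the sum of both. The titles and description labels of the blue sort from separately made virus and the green sort from pooled virus conflict, so those populations were grouped by title and matched to the table by its own sample names.

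Total depth was 32369777 UMIs in the pooled-virus mock library, 15448606 in the pooled-virus doxorubicin library, 15190515 in the arrayed-virus doxorubicin library, 146791807 in the CROP-seq mock library and 96100418 in the CROP-seq doxorubicin library. UMI counts were summed per library over all deposited barcodes, or per guide over cells with exactly 1 assigned guide. The metadata omitted 470 barcodes of the CROP-seq mock library and 404 of the CROP-seq doxorubicin library, and these entered only the sums per library. Cells with more than 1 guide and cells with none were left out of every guide comparison, and no doublet caller was run. The CROP-seq library held 183 guides, with 6 for each of 29 targets and 9 non-targeting controls. The barcoded library held 10 targets, of which only some had assigned cells in the arrayed-virus library. Comparisons and list results that need certain genes are not reported here.

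Counts were tested with edgeR 4.0.16 (TMM scaling, filterByExpr, quasi-likelihood test) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. Doxorubicin was tested over the 5 libraries with the vector as a block. Guides against each of 26 targets were compared with the 9 control guides within each CROP-seq library, using guides with at least 5 cells and targets with at least 3 such guides. Guides are separate constructs carried by separate cells of 1 culture, so these p-values measure the spread between guides and not between cultures. The share of cells per target was compared between doxorubicin and mock by a two-sided exact permutation test over guides, after adding 0.5 to each count, with adjustment over all targets. Single libraries were compared without a test, as log2 ratios of CPM (UMIs scaled to a common library total) for genes with at least 10 UMIs, with 95% intervals for counting error only. Interval bounds for list medians came from 2000 Poisson resamples. Each median was ranked among 10000 random lists, in which each member was replaced by a gene within 100 ranks of it in expression, list members included. Shares carry exact Clopper-Pearson 95% intervals. Amplicon reads carry no molecular identifiers, so all intervals cover counting error only. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used for these values.

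The gene lists, comparisons, tests, alternatives and the rule for named genes were chosen before the data were examined, except those stated in the closing section to have been chosen later. The lists reported were S phase, G2/M phase, replication-dependent histones, apoptosis, anti-apoptosis, DNA repair, NF-kB and inflammatory, interferon response, integrated stress response, heat shock, immediate early, oxidative stress, basal epithelial, luminal epithelial, squamous differentiation, mesenchymal, cholesterol synthesis, glycolysis, mitochondrially encoded, K562 and erythroid, lymphoid and myeloid, fibroblast, and ribosomal protein genes. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, and again with an estimated correlation. Named genes in the 5-library fit were those past the threshold with the same sign in both mock and doxorubicin pairs and at least 20 CPM in a library, ranked by the smaller change, up to 10 each way. Fewer than 10 rising genes passed, so that ranking was made without the adjusted p. For guide comparisons they were up to 3 genes for each of the 5 targets with most calls (ties in alphabetical order, which left out RB1 with 3 calls in doxorubicin), and for each list up to 4 members with the largest change. Genes singled out beyond this rule were chosen after their values were seen.

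The fit of doxorubicin over the 5 libraries was tested on simulated data with 200 changed genes. It recovered 0% of 2-fold and 7.27% of 4-fold changes, with 0 false calls. In a check of the list ratios, doubling the S phase or ribosomal genes returned log2 values of 0.99 and 0.75. The last value is below 1 because this list enlarges the library total, and it matched the value expected from that total; this expectation was added after the check had first been written without it. Alternatives were DESeq2 1.42.0, its size factors within edgeR, no filter on low counts, leaving out each library, at least 10 cells per guide, control-guide cells only, TMM-scaled CPM, and cells thinned to 5000 UMIs. Genome positions of the guides were not used here, since no reference sequence was searched.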

Results

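The 5 single-cell libraries were compared at the level of UMI counts. The pooled-virus libraries held 2775 mock cells with a median of 11611 UMIs and 2191 doxorubicin cells with a median of 7026 UMIs. The arrayed-virus doxorubicin library held 2274 cells with a median of 6371.5 UMIs. The CROP-seq libraries held 6598 mock barcodes with a median of 22595.5 UMIs and 6283 doxorubicin barcodes with a median of 15324 UMIs. Mitochondrially encoded transcripts took 2.33% of UMIs in pooled-virus mock and 2.52% in pooled-virus doxorubicin cells, 2.99% in arrayed-virus doxorubicin cells, and 2.31% and 2.93% in CROP-seq mock and doxorubicin cells. Every group had 1 library, so values for single libraries are given without replicate error. The 8 sorted populations were each read with between 27925 and 85289 amplicon reads.

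The sorted populations addressed how often a barcode is separated from the fluorescent protein it was built with when lentiviruses are packaged together. Only moves between a BFP and a GFP construct can be seen. A barcode that moves between like constructs stays with the same fluorescent protein, so the shares do not count every separation. Among BFP-sorted (blue) cells made with pooled virus, 9296 of 27925 reads carried the GFP-linked barcode, or 33.3% [32.7, 33.8], and among GFP-sorted (green) cells the BFP-linked barcode took 22.4% [22.1, 22.7]. With separately made viruses the shares were 1.02% [0.945, 1.10] in the blue sort and 7.47% [7.28, 7.66] in the green sort. Cells mixed after transduction, the background for sorting, gave 1.12% [1.03, 1.21] and 1.81% [1.71, 1.91]. Cells given 1 virus gave 0.206% [0.171, 0.245] and 0.232% [0.201, 0.267]. The mean over both sorts was 19.1-fold above the mixed cells for pooled virus and 2.90-fold for separate virus. For separate virus the excess was in the green sort, while the blue sort lay 0.913-fold relative to its mixed cells. The labels of the separate-virus blue and pooled-virus green populations conflict, and the contrast uses the names in the table. If these were exchanged, a green sort would carry mostly the BFP-linked barcode and a blue sort mostly the GFP-linked barcode, unlike all other sorts.

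**Figure D1:**
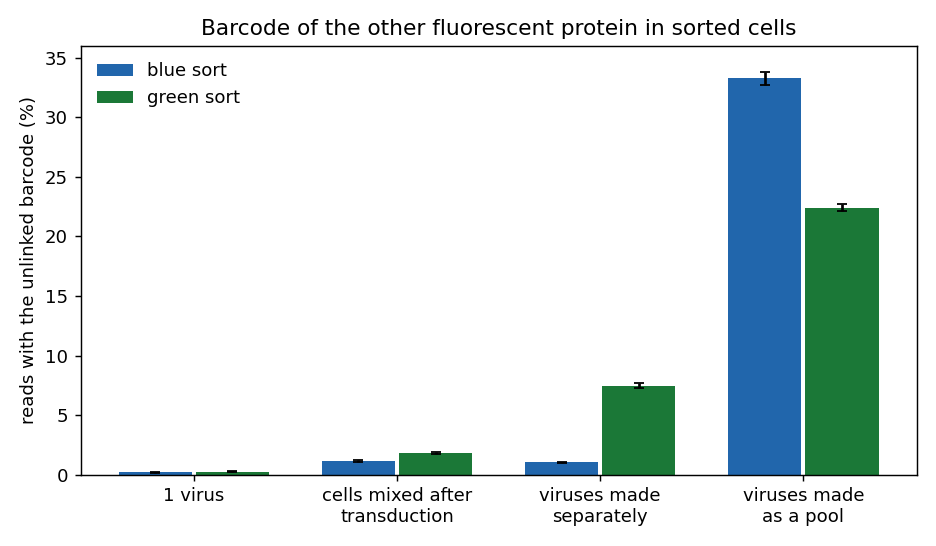
Percent of amplicon reads (vertical axis, from 0) with the barcode built with the other fluorescent protein, in blue and green sorts of cells made in 4 ways, 1 population per bar; lines are exact 95% intervals for counting error. Pooled virus gave 33.3% and 22.4%, against 1.12% and 1.81% in cells mixed after transduction.

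The share of cells with an assigned guide differed between libraries of unlike vector and virus production. CROP-seq shares are of the 6128 mock and 5879 doxorubicin cells in the metadata. These leave out 470 and 404 barcodes with low medians of 10179.5 and 6385 UMIs, while no barcodes of the barcoded-vector libraries were left out. Depth per cell and the number of targets also differed between libraries, so the shares are not a measure of vector or virus production alone. Exactly 1 guide was assigned to 77.3% [76.3, 78.4] of CROP-seq mock and 76.0% [74.9, 77.1] of CROP-seq doxorubicin cells. Exactly 1 barcode was assigned to 54.6% [52.7, 56.5] of pooled-virus mock and 51.7% [49.5, 53.8] of pooled-virus doxorubicin cells. In the arrayed-virus library it was 18.3% [16.8, 19.99], and 81.3% of cells had none. In that library cells at or above the median UMI count had 1 barcode in 27.9% of cases. Of its 417 cells with 1 barcode, 52 carried that of NCOR1 (12.5% [9.46, 16.0]) and 32 that of CBFB (7.67% [5.31, 10.7]), and none carried a control barcode.

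Doxorubicin was compared with mock over the 5 libraries, to describe the response of MCF10A cells to DNA damage. GDF15, a stress-induced secreted factor, rose by 7.72 (log2, SE 0.84, edgeR adjusted p = 0.0312), from 1.42 CPM in pooled-virus mock to 125 CPM with pooled virus and 574 CPM with arrayed virus, and from 0.865 to 143 CPM in CROP-seq cells. BTG2, an antiproliferative gene, rose by 4.02 and FDXR, a mitochondrial ferredoxin reductase, by 3.33 (both adjusted p = 0.0326). LCE1B, a cornified envelope gene, rose by 8.68 and AKR1B10, an aldo-keto reductase, by 5.67, and the histone genes HIST2H2BE and HIST2H2AA3 rose by 4.23 and 4.199 (adjusted p = 0.0312 to 0.0326). The linker histones HIST1H1A and HIST1H1D fell by 4.67 and 4.31. Of the G2/M list, the mitotic kinase PLK1 fell by 3.63, cyclin B1 (CCNB1) by 3.58, PSRC1 by 3.55, the anaphase activator CDC20 by 3.44 and CENPE by 3.35. Outside the lists, DEPDC1 fell by 3.72, cyclin A2 (CCNA2) by 3.26 and PHF19 by 3.18 (all adjusted p = 0.0312 to 0.0326). Other genes in the rising ranking missed the threshold: UNC5B-AS1 (5.99, adjusted p = 0.0588), PRODH (5.75, 0.0712), FXYD3 (5.69, 0.119) and PGF (4.59, 0.0523), with RP11-597D13.9. With 1 to 3 UMIs in pooled-virus mock, the pooled-pair log2 ratios of LCE1B, FXYD3, PRODH and UNC5B-AS1 were 6.71 [4.17, 12.04], 7.196 [4.67, 12.52], 5.95 [4.03, 9.03] and 5.73 [4.13, 8.04], and their fitted values depend on the prior count.

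In all, 40 of 15522 genes passed, 19 higher and 21 lower, with 3175 at an unadjusted p under 0.05. The design left few degrees of freedom, and DESeq2 called 1490, of which 58.9% were higher against 47.5% by edgeR. Without the pooled-virus mock library edgeR called 0 genes, without arrayed virus 7, without pooled-virus doxorubicin 141, and without the CROP-seq mock or doxorubicin library 3010 or 3678.

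By list, G2/M genes had the most calls. Of 55 G2/M genes, 10 were lower, PLK1, CCNB1, PSRC1 and CDC20 by most, and none was higher (46 lower adjusted over the list alone, median -2.26, camera adjusted p = 9.4e-44, adjusted p = 0.447 with an estimated correlation). None of 41 S phase genes passed over all genes, and 18 were lower adjusted over the list alone (median -1.21, camera adjusted p = 2.3e-12, adjusted p = 0.762 with an estimated correlation). DNA repair genes likewise had 0 of 26 past the threshold by edgeR, 8 lower adjusted over the list alone (median -0.99, camera adjusted p = 7.0e-08, adjusted p = 0.447 with an estimated correlation). Histone genes moved both ways, with HIST2H2BE higher and HIST1H1A and HIST1H1D lower among 16 (8 higher and 6 lower adjusted over the list alone, median 1.71, camera adjusted p = 0.710). The lymphoid and myeloid list had a median of 2.48 over 6 genes (camera adjusted p = 0.0175, adjusted p = 0.762 with an estimated correlation), none past the threshold. Its members stayed at a few CPM, CD14 going from 0.587 to 6.60 CPM and CD3D from 0 UMIs, which allows up to 3 UMIs of the library, to 4.08 CPM in the pooled-virus pair. In the CROP-seq pair CD14 went from 2.83 to 2.56 CPM and CD3D from 2 to 0 UMIs, and the list median was 0.45 [0.02, 0.95] against 3.11 [2.70, 3.95] in the pooled-virus pair.

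No member of the other lists passed over all genes, and no camera call was made for them. Adjusted over the list alone, 2 apoptosis genes, 2 integrated stress response genes and 1 gene each of the basal, mesenchymal and NF-kB lists were higher, and 1 gene each of the anti-apoptosis, NF-kB, interferon, integrated stress response, heat shock and cholesterol lists was lower. Median log2 changes were 0.29 for apoptosis (19 genes, camera adjusted p = 0.252), -0.48 for anti-apoptosis (8, 0.413), -0.04 for NF-kB and inflammatory genes (18, 0.991; mean 0.31), 0.54 for interferon response (16, 0.413), -0.11 for the integrated stress response (15, 0.590, mean 0.38 and camera direction up), -0.76 for heat shock (11, 0.122), -0.62 for immediate early genes (13, 0.413) and 0.42 for oxidative stress (12, 0.711). They were 0.40 for basal (13, 0.534), 1.07 for luminal (9, 0.445), 0.32 for squamous (11, 0.534) and 0.04 for mesenchymal genes (12, 0.966). They were 0.48 for cholesterol synthesis (11, 0.711), 0.36 for glycolysis (11, 0.711), 0.20 for mitochondrially encoded genes (13, 0.770), 0.16 for ribosomal protein genes (77, 0.567), 1.43 for K562 and erythroid genes (2, 0.482) and 0.08 for fibroblast genes (3, 0.770).

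The pairs of mock and doxorubicin libraries with the same vector and virus were set side by side; their doses differed. In the CROP-seq pair at 100 nM, all 55 G2/M genes were lower with doxorubicin (median log2 ratio -3.15 [-3.19, -3.05]) and all 41 S phase genes were lower (-1.83 [-1.86, -1.76]). In the pooled-virus pair at 500 nM, 3 of 55 G2/M genes were higher with a list median of -1.61 [-1.72, -1.48], and 12 of 41 S phase genes were higher with a median of -0.83 [-0.99, -0.63]. Both G2/M medians ranked below all 10000 random lists.

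DNA repair genes had medians of -0.90 [-0.95, -0.84] in the CROP-seq pair and -1.002 [-1.16, -0.93] in the pooled-virus pair, and histone genes 0.87 [0.73, 1.02] and 1.15 [1.02, 1.52]. Basal epithelial genes had 0.46 [0.44, 0.48] and 0.60 [0.53, 0.63]. Heat shock genes had -0.63 [-0.71, -0.56] and -0.68 [-0.79, -0.55], and anti-apoptosis genes -0.38 [-0.43, -0.34] and -0.63 [-0.75, -0.52]. Among random lists of like expression, heat shock ranked at 0.05% and 13.2% and anti-apoptosis at 16.0% and 24.6%. NF-kB and inflammatory genes had 0.24 [0.05, 0.30] and 0.47 [0.33, 0.64], and interferon response genes 0.27 [0.11, 0.47] and 0.64 [0.54, 0.94]. Immediate early genes had -0.13 [-0.18, -0.09] and -0.95 [-1.16, -0.84], and ranked at 66.5% and 8.45% among random lists. Of 23 lists, 6 had medians on opposite sides of 0 in both pairs beyond counting error. Ribosomal protein genes had 0.18 [0.17, 0.19] in the CROP-seq pair, with 64 of 78 higher, and -0.14 [-0.16, -0.12] in the pooled-virus pair, with 29 of 77 higher. Against random lists of like expression the ribosomal median ranked low in both pairs, at 3.92% and 0%. These random lists could draw ribosomal genes themselves, so the ranks do not set the list against other genes alone. Mitochondrially encoded genes had 0.24 [0.23, 0.33] with 9 of 13 higher, and -0.09 [-0.11, -0.07] with 6 of 13 higher, while their share of UMIs rose in both pairs. In the pooled-virus pair TMM scaling moved all genes by 0.16. In control-guide cells of that pair the luminal and squamous medians changed sign, from 1.77 to -0.90 and from 2.07 to -2.49. Those 192 mock and 128 doxorubicin cells are known only by a linked barcode, and the pooled-virus sorts had 33.3% and 22.4% of reads with the other barcode, so the cells are not known to carry control guides alone. Medians take only genes with at least 10 UMIs, and these cells hold fewer UMIs, so the medians may rest on fewer members. In all cells of the pair KRT10, the most abundant squamous gene, fell from 511 to 95.6 CPM. Among the abundant luminal genes KRT7 fell from 1912 to 926 CPM, KRT18 from 218 to 108 and MUC1 from 19.9 to 13.5. KRT8 rose from 64.0 to 110 CPM and GATA3 from 16.7 to 56.6.

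**Figure D2:**
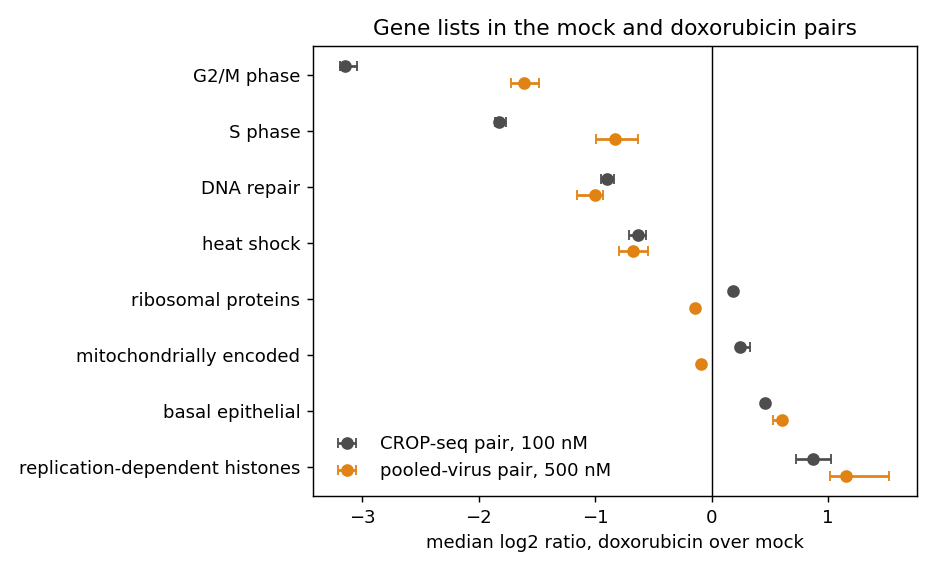
Median log2 ratio of doxorubicin over mock (horizontal axis) for 8 gene lists (vertical axis) in the CROP-seq pair at 100 nM and the pooled-virus pair at 500 nM; lines are 95% intervals for counting error in 1 library per group. G2/M genes had the lowest medians of these lists, -3.15 and -1.61, and ribosomal protein genes lay at 0.18 and -0.14.

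Guides against 26 of the CROP-seq targets were compared with 9 control guides. Few genes passed. In doxorubicin 10 targets had 31 calls in all and 16 had none by edgeR, and DESeq2 made 12 calls. Of 4462 to 5710 genes tested per target, 195 to 367 had an unadjusted edgeR p under 0.05 (median 262.5). In mock 5 targets had 14 calls and 21 had none by edgeR, and DESeq2 made 7 calls. There 222 to 538 of 5461 to 7109 tested genes had an unadjusted edgeR p under 0.05 (median 338.5). Chance alone puts a share of about 0.05 of tested genes there, and both medians lie near that share. With doxorubicin, guides against PTPN22, a tyrosine phosphatase, had lower POSTN (-1.86, SE 0.35) and IL32 (-1.88, SE 0.40) and higher LCE1B (1.33, SE 0.28), each on that side in 5 of 5 guides. POSTN stood at 12.4 ± 11.5 CPM (SD, n = 5) against 63.6 ± 33.6 CPM in control guides (n = 9). Guides against the kinase gene STK11 had higher AKR1C2 (1.98), KRT6B (1.21) and KYNU (0.70), with AKR1C2 and KRT6B higher in 4 of 6 guides and KYNU in 3 of 6, and AKR1C2 at 51.8 ± 39.4 against 16.2 ± 4.69 CPM. Guides against ARID1B, a chromatin remodelling subunit, had higher TK1 (1.05), CDKN3 (1.38) and KIAA0101 (0.79), each in 5 of 6 guides. In doxorubicin DESeq2 called 0 genes for STK11 and for ARID1B, while with at least 10 cells per guide their calls rose from 6 to 12 and from 5 to 9. The 6 calls for PTPN22 fell to 2 with at least 10 cells per guide and to 3 with DESeq2. Its 5 guides held only 80143 to 422386 UMIs each. The metallothioneins MT1E (-0.46) and MT1X (-0.60) were lower and RPL3 (0.17) higher in all 6 guides against CHEK1, a checkpoint kinase gene, with MT1E at 401 ± 69.99 against 592 ± 56.5 CPM (edgeR adjusted p = 0.00533). MT2A (-0.35), MT1E (-0.40) and ESF1 (-1.23) were lower in all 6 PTPRD guides, with ESF1 at 15.4 ± 5.33 against 38.1 ± 5.29 CPM (edgeR adjusted p = 0.0242). The CHEK1 and PTPRD comparisons share the same 9 control guides, so the MT1E calls of both are not independent. In doxorubicin PTPN22 and PTPRD had 0 UMIs of their own mRNA in target and control guides, which allows up to 3 UMIs in each. The targeted mRNA was thus not detected in control guides either, and these calls cannot be read as effects of its loss. In mock PTPN22 had 0 UMIs in target and 6 in control guides, and PTPRD 0 in both.

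In mock, STK11 guides had lower IGFBP3 (-1.19) and higher AKR1C1 (1.00) and HSD17B2 (0.85), each in 6 of 6 guides, with IGFBP3 at 21.8 ± 12.4 against 53.4 ± 16.8 CPM (edgeR adjusted p = 0.00435). The 8 mock calls for STK11 fell to 2 with at least 10 cells per guide and to 1 with DESeq2. ARID1B guides had higher KIF23 (0.53) and NF2 (0.54), SETD2 guides lower TAGLN (-0.48) and S100A14 (-0.50), MLL2 guides lower SLPI (-0.42) and NF1 guides lower S100A2 (-0.28). For STK11 in doxorubicin and for SETD2, MLL2 and NF1 in mock, at least 2 of 40 splits of the guides, the real one included, gave as many genes. With at least 10 cells per guide the 26 targets had 48 calls in doxorubicin and 10 in mock. Of 520 list tests per library, camera called 102 in doxorubicin and 144 in mock, and 0 and 3 with an estimated correlation. The mRNA of the targeted gene itself was called for 0 of 7 tested targets in doxorubicin and 0 of 18 in mock by edgeR, with 0 and 4 at an unadjusted p under 0.05.

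The share of single-guide cells per target was compared between doxorubicin and mock over guides. NCOR1 cells made up 4.51% in mock and 3.00% in doxorubicin, a log2 difference from control guides of -0.66, lower in 6 of 6 guides (exact permutation p = 0.00240, adjusted p = 0.0695). RB1 had -0.42, lower in 5 of 6 guides (exact p = 0.0276, adjusted p = 0.1999), BRCA2 0.51, higher in 6 of 6 guides (exact p = 0.0190, adjusted p = 0.183), and NF1 0.58, higher in 5 of 6 guides (exact p = 0.0494, adjusted p = 0.286). None of the 26 targets passed after adjustment.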

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

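The tests of depth and scaling, the search for lists of opposite sign, and the counts of other splits were chosen after the result was seen.

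For each target with named genes 40 splits of the guides, the real one included, were drawn from 2002 or 5005 possible ones. In doxorubicin no other drawn split called as many genes for PTPN22 (6 genes, highest other 1), ARID1B (5, highest other 3), CHEK1 (3, highest other 1) and PTPRD (3, highest other 1). The same held in mock for STK11 (8, highest other 1) and ARID1B (2, highest other 1), each with 1 split as large, the real one. These targets were picked for their calls among 26 targets, for which the splits make no allowance. Few of the possible splits were drawn, so chance is not excluded. In doxorubicin the mRNA of PTPN22 and PTPRD was not detected in control guides, so their calls cannot be read as effects of its loss. For ARID1B DESeq2 called 0 genes in both libraries, PTPN22 had 2 genes with at least 10 cells per guide, and STK11 in mock had 2 genes with at least 10 cells per guide and 1 with DESeq2. With at least 10 cells per guide ARID1B in doxorubicin rose to 9 genes and STK11 in doxorubicin to 12. Other drawn splits did call as many genes for STK11 in doxorubicin (6 genes, highest other 6, 2 splits as large). They also did in mock for SETD2 (2 genes, highest other 6, 6 splits as large), MLL2 (1 gene, highest other 5, 8 splits as large) and NF1 (1 gene, highest other 3, 5 splits as large). For SETD2, MLL2 and NF1 other splits called more genes than the real one, and structure among the guides was not tested.

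The same 9 control guides were searched for single guides far from the others, over several measures in both CROP-seq libraries. Such a guide was found in 3 of 22 searches, against 1.1 if chance alone puts about 1 in 20 there. The searches share their guides and the measures overlap, so this expectation is only rough. All 3 are control guide 4, which had 8 cells in doxorubicin and 12 in mock, the fewest of the 9 control guides. In doxorubicin control guide 4 had 2.60% of UMIs on mitochondrially encoded genes, the others 2.82% to 2.97%. In mock control guide 4 had 19.7% on ribosomal protein genes, the others 18.2% to 18.7%, and a mean log2 CPM of 11.22 over them, the others 11.13 to 11.16.

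Of 23 lists, 6 had medians on opposite sides of 0 in the pairs of mock and doxorubicin libraries beyond counting error; the difference itself was not tested. The medians in the CROP-seq pair at 100 nM and the pooled-virus pair at 500 nM were -0.16 and 0.42 for apoptosis, -0.13 and 0.35 for the integrated stress response, 0.24 and -0.0918 for mitochondrially encoded, -0.34 and 5.82 for K562 and erythroid, -0.49 and 0.88 for fibroblast, and 0.18 and -0.14 for ribosomal protein genes. The K562 and erythroid and the fibroblast list rest on 3 genes each, and the former on few UMIs, with HBA1 at 4 UMIs in pooled-virus mock and 42 in pooled-virus doxorubicin.

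The ribosomal and mitochondrially encoded lists, the abundant ones among these, were weighed further. An unequal weight of deep and shallow cells is argued against, but other effects of depth stay open. Thinning leaves the expected proportions of genes within each cell unchanged. It also left out 140 mock and 465 doxorubicin cells of the pooled-virus pair, and 29 mock and 124 doxorubicin barcodes of the CROP-seq pair. With each cell thinned to 5000 UMIs, the ribosomal medians were 0.16 [0.15, 0.17] in the CROP-seq pair and -0.15 [-0.18, -0.12] in the pooled-virus pair, and the mitochondrially encoded medians 0.21 [0.195, 0.30] and -0.12 [-0.15, -0.09]. Scaling by the library total stays open. With TMM scaling, which shifts all genes of a pair alike, these medians were 0.21 [0.197, 0.21] and -0.30 [-0.32, -0.28] for ribosomal, and 0.27 [0.26, 0.35] and -0.25 [-0.27, -0.23] for mitochondrially encoded genes. Against random lists of like expression the ribosomal median ranked low in both pairs, at 3.92% and 0%. The mitochondrially encoded median ranked at 69.3% and 14.6%, neither at an extreme. Members were not left out of the random lists, so the ranks do not set either list against other genes alone and cannot settle the scaling. The mitochondrially encoded share of UMIs rose in both pairs, and the opposite sign there holds for the median gene only.

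For the other 4 lists depth per cell stays open, since in thinned cells the CROP-seq medians were -0.12 [-0.37, 0.08] for apoptosis, -0.12 [-0.22, 0.01] for the integrated stress response, -0.57 [-1.54, 0.24] for K562 and erythroid and -0.36 [-0.67, 0.09] for fibroblast genes. The pooled-virus medians in thinned cells stayed above 0, at 0.57 [0.47, 0.88], 0.43 [0.14, 0.63], 4.38 [2.81, 6.34] and 0.93 [0.46, 1.07]. Scaling stays open for them too. The TMM medians were 0.19 [-0.15, 0.32] for the integrated stress response in the pooled-virus pair and -0.31 [-0.69, 0.02] for K562 and erythroid genes in the CROP-seq pair. Apoptosis genes had -0.13 [-0.27, -0.01] and 0.26 [0.19, 0.67], and fibroblast genes -0.46 [-0.63, -0.22] and 0.72 [0.68, 0.78]. Dose, vector and culture differ together between the pairs and stay open as sources of the difference. A response that changes with dose may contribute and remains a hypothesis, which no comparison here tested apart from the others.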

How the results depend on the processing

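The alternatives of cells in the metadata only and all cells with a guide of the target were chosen after seeing the data. No target passed for cell shares by the exact permutation test with all cells of the target or with at least 10 cells per guide over both libraries. Of 1509 further values for single genes, lists and targets under alternatives, 1162 kept their side of the threshold or moved within their error. Of the rest, 201 passed newly, 61 no longer passed, 83 moved further and 2 reversed. Direction was checked only for values that passed the threshold or, in the pairs, lay beyond counting error, so other changes of sign are not counted.

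Doxorubicin over the 5 libraries gave 1490 genes with DESeq2, 1270 with no filter on low counts, 1 with control-guide cells only, which also drops the arrayed-virus library for want of such cells, and 0 to 3678 when leaving out 1 library at a time. The lone library of a group is then assumed to vary like the others, and leaving out an arm of a vector leaves doxorubicin to be judged in the other vector; the cause of these changes was not tested. The 26 targets had 48 calls in doxorubicin with at least 10 cells per guide and 12 with DESeq2, against 31, and 7 in mock with DESeq2, against 14; the cause was not tested. Both S phase and G2/M medians stayed below 0 in both pairs under every alternative run. In the CROP-seq pair they were -2.20 and -3.60 in control-guide cells and -1.93 and -3.27 in thinned cells. In the pooled-virus pair they were -0.99 and -1.77 with TMM scaling and -0.58 and -1.38 in thinned cells. In control-guide cells of that pair the luminal median reversed to -0.90 and the squamous median to -2.49. These cells are known only by a linked barcode. They hold fewer UMIs, so fewer members may reach 10 UMIs, and the cause was not tested.

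Subtracting the mixed-cell share gave 32.2% and 20.6% unlinked reads for pooled virus in the blue and green sorts, and -0.0968% (reversed) and 5.66% for separate virus, as follows from the subtraction. Subtracting the single-virus share gave 0.812% and 7.24% for separate virus. Means over both sorts were 27.9% for pooled and 4.24% for separate virus. At or above the median UMI count, exactly 1 guide was assigned to 71.5% of CROP-seq doxorubicin, 73.3% of CROP-seq mock and 27.9% of arrayed-virus cells. Any guide was assigned to 94.98% and 95.5% of CROP-seq doxorubicin and mock cells and to 67.2% and 76.0% of pooled-virus doxorubicin and mock cells.

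Choosing the best-supported guide of cells with several was not run. Size factors of DESeq2, no filter on low counts, other comparison guides and leaving out single guides were not run for the 26 targets. Of the 26 targeted mRNAs 7 were tested in doxorubicin and 18 in mock; PTPN22, PTPRD and CDKN2A had 0 UMIs in target and control guides in doxorubicin.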

Other observations

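Values in this part were chosen after they were seen. The barcoded-vector and CROP-seq mock cells, both MCF10A by label, differed in lineage genes. Of genes with at least 10 UMIs over both, all 13 genes of the basal list were lower in pooled-virus mock, and 7 of 9 luminal genes were lower, among them EPCAM at 0.185 against 18.3 CPM. Mesenchymal genes went both ways, with 8 of 12 higher, among them FN1 at 982 against 213 CPM, and TAGLN lower at 435 against 733 CPM. The basal keratins KRT5 and KRT14 were at 100.5 and 101.5 CPM in pooled-virus mock against 561.5 and 1189 CPM in CROP-seq mock, and KRT17 was at 0.0618 (2 UMIs) against 48.4 CPM. TP63, the basal transcription factor, had 0 UMIs, which allows up to 3, against 871 UMIs (5.93 CPM). Total depth alone does not account for these differences, since the CPM are scaled for it and 32369777 UMIs were read in pooled-virus mock. Depth per cell also differed, with medians of 11611 UMIs in pooled-virus mock and 22595.5 in CROP-seq mock. The mock libraries were not compared in thinned cells, so other effects of depth stay open. Vector and culture differ together between these libraries, and no test was made of them.

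IL6, an inflammatory cytokine gene, was at 0.185 CPM in pooled-virus mock and 23.8 CPM in pooled-virus doxorubicin cells, against 0.0886 and 0.166 CPM in the CROP-seq pair; it did not pass over the 5 libraries (edgeR adjusted p = 0.193). In the same pooled-virus pair SNAI2, a mesenchymal transcription factor, went from 103 to 7.06 CPM, while in the CROP-seq pair it was 136.8 and 137.02 CPM. The DNA break sensor gene NBN went from 51.2 to 2.07 CPM in the pooled-virus pair and from 61.3 to 24.7 CPM in the CROP-seq pair (adjusted p over the 5 libraries = 0.102).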
